A study of Mus musculus with 3 samples.

How the data were processed

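Messenger RNA was measured in 3 pooled libraries of cells sorted by flow cytometry from the epithelium of the upper small intestine of C57BL/6 mice. Per the labels' protocols, the villus fraction was released with EDTA and dispersed with collagenase, individual RNA samples were combined in equal amounts for each library, polyadenylated RNA was converted to cDNA without amplification of the RNA, and TruSeq libraries were read on a Genome Analyzer II. The number of mice in each pool is not given in the sources used here. The groups were GIP-GFP (cells of a reporter mouse that express the incretin hormone GIP), Ngn3-TOMATO (cells that carry the tomato reporter because they or their progenitors expressed Neurogenin 3, the factor that starts enteroendocrine differentiation) and Ngn3-negative (tomato-negative epithelial cells). Per the series' design text, the tomato sorts used male mice and excluded cells stained for CD45, a marker of blood cells. That text states no such gate for the GIP-GFP sort.

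The deposited files hold 1 line per UCSC transcript model, with the same 59120 transcripts in each library. Reads were checked with FastQC, TopHat 1.5.0 and Cufflinks were used, and the genome build was mm10, per the submitters' processing notes. The version of Cufflinks is not given in the sources used here. Per the file headers, the authors deposited for each transcript its length, its coverage (mean read depth per base), its FPKM (by name, fragments per kilobase of transcript and unit of library size), a lower and an upper limit of the FPKM, and a status. The deposited FPKM summed to 10160000000 in GIP-GFP, 10740000000 in Ngn3-TOMATO and 10370000000 in Ngn3-negative, far above what that unit would give, and FPKM was a constant multiple of coverage within a library (29553 in GIP-GFP, 12249 in Ngn3-TOMATO and 16284 in Ngn3-negative). The library term was therefore not the one the name states, and which term was used is not given in the sources used here. The status was OK for 58545, 58104 and 58277 transcripts in these libraries, in that order. It was HIDATA, meaning too many reads to process, for 0, 4 and 9 transcripts, whose listed value of 0 was treated as missing. These were 3 transcripts of the goblet cell gene Fcgbp and the mitochondrial mt-Co1 in Ngn3-TOMATO, and 6 mitochondrial transcripts, Gm10925, Gm26917 and Myo3a in Ngn3-negative. Mitochondrial transcripts were left out of all comparisons.

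The files name no genes. Transcripts were matched without strand to GENCODE M21, an annotation of the same genome sequence, by their ends, spliced length and overlap, and 52204 of the 59120 received a gene symbol. Transcripts without a symbol held 2.53% of the read bases in GIP-GFP, 1.95% in Ngn3-TOMATO and 0.712% in Ngn3-negative. These shares are not comparable between libraries. An abundant mitochondrial transcript without a symbol, uc009vfc.1, counts in GIP-GFP and Ngn3-TOMATO but had status HIDATA and a listed 0 in Ngn3-negative. Transcripts under 200 bases were left out, because their length correction is unstable and they held 9.07%, 15.8% and 20.3% of the summed FPKM in the same order. The remaining deposited FPKM were summed per gene symbol and divided by 1 common number, 8218, so that the mean total over genes was 1000000 per library. This division leaves every ratio between libraries as deposited and is called scaled FPKM. It was needed because the planned pseudocount and filter of 1 FPKM have no weight on the deposited scale. The calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and the plots matplotlib 3.10.9. Coordinates are 1-based on mm10 as the files give them, for the most abundant transcript of a gene.

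No library was repeated, so no test between groups and no p-value is given. Genes at 1 scaled FPKM or more in at least 1 of the 2 libraries were compared as log2 of the ratio of values after a pseudocount of 1 was added to each, which understates the difference for low genes. Folds are on this scale. Genes past 2-fold and 4-fold were counted. A 95% counting interval for each log2 ratio was computed from the deposited FPKM limits, taken as 2 standard errors. It covers counting and read assignment within these libraries and not the difference between mice or sorts. The depth, as the sum of coverage times length over the listed transcripts, was 592.1 Mb in GIP-GFP, 1380 Mb in Ngn3-TOMATO and 1030 Mb in Ngn3-negative. Transcripts with status HIDATA add nothing to these sums, which are therefore too low in Ngn3-TOMATO and Ngn3-negative. Whole fragment counts could not be recovered: squaring the ratio of FPKM to its standard error gave a whole number, within 0.01, for 35.1%, 39.5% and 40.0% of transcripts estimated at under 60 fragments.

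31 gene lists were fixed before the data were examined. For each list, the median log2 ratio of its members was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. The percentile describes these libraries and tests no condition. A list is called outside the random range when its median lies beyond the middle 95% of the random lists. Some genes stand in more than 1 list. Named genes followed a rule fixed at the same time: Gip and Neurog3 first, then the 12 genes with the highest and the 12 with the lowest log2 ratio among named genes at 10 scaled FPKM or more in the higher library, then for each list its most abundant member and the 2 to 4 members farthest from 0. The text gives a part of the genes that this rule takes for the lists. Several of these turned out to be listed at exactly 0 in 1 library while being used by every cell. In GIP-GFP, 16 genes were listed at 0 that stood at 10 or more in both other libraries, against 9 in Ngn3-TOMATO and 34 in Ngn3-negative, mostly with status OK. An exact 0 may thus be a failed estimate, and no fold is given for one. The count for Ngn3-negative also takes in the hormone gene Gast, and true absence was not separated from failed estimates. The ranking was then repeated among genes above 0 in both libraries, a choice made after seeing the data. Slc6a19 and Tph1 in GIP-GFP against Ngn3-negative, and Cck, Ghrl, Gpr119, Pyy, Sct and Sst in GIP-GFP against Ngn3-TOMATO, were named outside the rule, after their values were seen. Gpx3 and Pdk4, named for the patterns over all 3 libraries, also stand outside the rule.

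The comparison was checked on simulated data, with the changed genes drawn from those at a mean of 5 scaled FPKM or more. The simulated noise was counting error only, without differences between mice, sorts or lines and without failed estimates. The rates below therefore describe the calculation and not the error in these data. With 200 genes set 4-fold apart among 13067 genes simulated for Ngn3-TOMATO against Ngn3-negative, 200 were recovered and 12 of 12867 equal genes passed 2-fold. For GIP-GFP against Ngn3-negative, 200 of 200 were recovered among 13115 genes and 38 of 12915 equal genes passed. For GIP-GFP against Ngn3-TOMATO, 199 of 200 were recovered among 13424 genes and 28 of 13224 equal genes passed. Of 100 lists drawn without a difference, 6, 5 and 4 lay outside the random range in the same order. The other settings fixed in advance were pseudocounts of 0.1 and 5, no filter or a filter at 5, 3 other scalings between libraries (equal totals, the median ratio over genes at 5 or more in every library, and equal totals without the 20 most abundant genes of each library), the most abundant transcript in place of the sum, non-overlapping deposited limits of that transcript, and only transcripts with status OK. Added after seeing the data were the inclusion of transcripts under 200 bases, only matches that share a transcript end, and the removal of genes listed at 0.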

Results

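The data are 3 transcriptomes of sorted epithelial cells from the mouse upper small intestine, with 1 pooled library in each group. GIP-GFP holds cells that make the incretin GIP, Ngn3-TOMATO holds the lineage of Neurogenin 3-expressing progenitors, from which the hormone-secreting enteroendocrine cells arise, and Ngn3-negative holds the remaining epithelial cells. The study set out to describe the transcriptome of GIP cells beside that of the whole enteroendocrine lineage and of the other epithelium. The libraries held 592.1, 1380 and 1030 Mb of read bases over the listed transcripts in that order, without the transcripts that had too many reads to process. Genes at 1 scaled FPKM or more numbered 13039 in GIP-GFP, 13134 in Ngn3-TOMATO and 11971 in Ngn3-negative. With 1 library per group no difference below has a replicate check, and intervals are 95% counting intervals within these libraries.

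The reporter genes were read first. Gip (transcript uc007lba.1, chromosome 11, 96024545 to 96030828) stood at 239500 scaled FPKM in GIP-GFP, 27790 in Ngn3-TOMATO and 723.7 in Ngn3-negative. It took 23.0% of the summed gene values of the GIP-GFP library, which leave out mitochondrial transcripts and those with too many reads to process. Among the genes kept, the most abundant of both other libraries was the goblet cell lectin Zg16, with 8.39% in Ngn3-TOMATO and 1.74% in Ngn3-negative. Neurog3 (uc007fgu.1, chromosome 10, 62133090 to 62134763), which is expressed briefly in progenitors, stood at 4.44, 23.8 and 13.7 scaled FPKM in GIP-GFP, Ngn3-TOMATO and Ngn3-negative. Its log2 ratio of Ngn3-TOMATO to Ngn3-negative was 0.75 (0.54 to 0.96), and that of GIP-GFP to Ngn3-TOMATO was -2.19 (-2.61 to -1.78). The sex-linked genes had list medians of 0.13 for Ngn3-TOMATO and 0.22 for GIP-GFP against Ngn3-negative and 0.00 between the reporter libraries, all inside the random range. Scaling to equal totals turned the first of these below 0 and the median ratio the last.

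The first comparison, Ngn3-TOMATO against Ngn3-negative, asks what sets the enteroendocrine lineage apart from other cells of the same sort. Genes for gut hormones, their granules and their release were higher in Ngn3-TOMATO almost without exception among those measured. The median hormone gene was 46.2-fold higher (log2 5.53), and 15 of 16 measured hormone genes were at least 2-fold higher. Which cells of the Ngn3-negative sort held its hormone and granule transcripts was not tested. Any enteroendocrine cells left in that sort would lower these folds, so they compare sorts and not pure cell types. Goblet and Paneth cell genes were also higher in Ngn3-TOMATO, with medians of 4.10-fold and 5.43-fold, while absorptive enterocyte genes were a median of 4.20-fold lower and cell cycle genes 2.69-fold lower. Over all 13436 genes, 2583 were at least 2-fold higher and 1329 at least 2-fold lower, with 1188 and 251 past 4-fold. Of these 2-fold differences 66.0% were in the higher direction, against 53.4% when the libraries were scaled to equal totals. With a pseudocount of 5 the genes at least 2-fold higher numbered 1499. Of the 2583 higher genes 215 were listed at 0 in 1 library, as were 65 of the 1329 lower.

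Precursors of several gut peptides were far above Ngn3-negative. Ghrl, the ghrelin precursor (uc009dhl.1, chromosome 6, 113716119 to 113719880), was at 7284 scaled FPKM in Ngn3-TOMATO and 77.5 in Ngn3-negative, a log2 ratio of 6.54 (6.32 to 6.76). Cck, the cholecystokinin precursor (uc009sdg.2, chromosome 9, 121489824 to 121495689), was at 15850 and 182.2, a log2 ratio of 6.44 (6.35 to 6.52). Sst, the somatostatin precursor, was at 18280 and 256.8. Gip itself was 38.4-fold higher. Gast, the gastrin precursor, was at 670.8 and was listed at 0 in Ngn3-negative. All 18 measured genes of the secretory granule were at least 2-fold higher, with a median log2 ratio of 5.32, led by the granins Chga (8766 against 123.9) and Chgb (12000 against 190.7). The regulated exocytosis list had a median of 3.50 with 22 of 23 genes higher, and its most abundant member was the SNARE protein gene Snap25, at 216.2 against 3.14. The serotonin and enterochromaffin list had a median of 5.55 with 13 of 14 genes higher. In it Tph1, the rate-limiting enzyme of serotonin synthesis, was at 1993 against 29.7, the irritant-sensing channel gene Trpa1 at 246.7 against 2.87, and Reg4 at 12100 against 180.3. Cartpt, a neuropeptide precursor, was at 230.2 against 2.65.

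Of 27 enteroendocrine transcription factors 23 were higher, with a median of 3.50. Neurod1 was at 601.9 against 11.2, Fev at 168.9 against 2.54, Lmx1a at 134.7 against 2.14 and Isl1 at 146.7 against 3.22. The list of hormone and transmitter receptors had a median of 2.36 with 19 of 25 higher and 1 lower, including the somatostatin receptor Sstr1 at 194.6 against 3.53 and the GLP-1 receptor Glp1r at 42.3 against 0.392. Nutrient sensing genes had a median of 1.92 with 10 of 18 higher and 2 lower, among the higher the fatty acid receptors Ffar1 (64.6 against 1.70) and Ffar2 (108.5 against 4.84), while the glucose transporter Slc5a1 was lower (235.2 against 1015). Genes of glucose sensing and excitability had a median of 2.81 with 23 of 27 higher, including Abcc8, a subunit of the ATP-sensitive potassium channel, at 82.2 against 1.89. The neuron and glia list had a median of 2.89 with 7 of 10 higher, and the members farthest from 0 were Th, Ret, Nefm and Nefl. Over the other settings the lowest medians were 0.418 for nutrient sensing, 0.89 for receptors and 1.03 for neurons and glia. These lists stayed outside the random range under all of those settings. The Notch list had a median of 0.54, at percentile 93.8 of the random lists, with the ligand genes Jag2 (23.4 against 2.03) and Dll4 (99.3 against 12.8) higher.

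All 19 measured goblet cell genes were at least 2-fold higher in Ngn3-TOMATO, led by Zg16 (uc009jue.1, chromosome 7, 127050156 to 127051977), at 89110 against 15640 scaled FPKM, the trefoil peptide gene Tff3 at 58400 against 10250 and the mucin gene Muc2 at 6987 against 1403. Fcgbp could not be compared because its reads exceeded the limit of the quantification in Ngn3-TOMATO. Of 18 Paneth cell genes 17 were higher and 1 lower, the higher including lysozyme, Lyz1, at 6921 against 1161 and the defensin gene Defa24 at 15570 against 2787. Defensin genes are near-identical copies that share reads, so the split among them is uncertain. The tuft cell list had a median of 0.84 with 5 of 21 genes past 2-fold. Enterocyte brush border genes were lower for 27 of 34, with a median of -2.07, among them the adenosine deaminase gene Ada (42.9 against 518.5), the enteropeptidase gene Tmprss15 (1.49 against 22.5) and Rbp2 (1144 against 4695). Lipid absorption genes had a median of -1.34 with 23 of 34 lower and 3 higher, and the apolipoprotein genes Apoa4 and Apoa1 were at 671.4 against 5482 and 1511 against 9537. Among the higher was the scavenger receptor gene Scarb1 (97.6 against 12.6).

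Cell cycle genes were lower for 32 of 33 members, with a median of -1.43. Top2a was at 38.1 against 117.1 and Birc5 at 35.2 against 109.9. Tk1 was listed at 0 in both reporter libraries. The stem cell list, inside the random range, had a median of -0.28, with Olfm4 at 1028 against 2629. Genes of oxidative phosphorylation were lower by a median of 2.01-fold and those of MHC class II by 4-fold, with 7 of 7 lower. The Reg family and erythroid genes had medians of -1.83 and -1.99, and all 4 of these lists lay below the random range. The immediate early genes, which tissue dissociation can induce, were higher by a median of 3.90-fold with 20 of 26 past 2-fold and 1 lower, for example Nr4a1 at 426 against 14.2 and Fos at 2011 against 518.4. Unfolded protein response genes had a median of 0.26 with 2 of 24 past 2-fold. Lymphocyte genes had a median of -0.89 with 7 of 19 lower. The lists for B cells, myeloid cells and stroma had medians of -0.19, 0.04 and 0.56, inside the random range, the myeloid median changing sign with the scaling, although Vim was at 294.6 against 7.92. Housekeeping genes had a median of -0.41 and epithelial identity genes -0.08, both inside the random range, and the epithelial median turned above 0 under the median ratio and under equal totals without the most abundant genes. The fatty acid binding protein list had a median of -0.33, inside the random range, with Fabp5 at 154 against 5.51 and the enterocyte form Fabp2 at 2175 against 11130.

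The genes highest over Ngn3-negative also included Afp, the fetal serum protein alpha-fetoprotein, at 1830 against 15.2 scaled FPKM (log2 6.82, 6.69 to 6.96), the plasma protein precursor gene Ambp at 889.1 against 9.65 and the receptor gene Adgrg4, a member of the serotonin list, at 432.7 against 5.39. Vti1b, Tnfrsf12a and Bace1 were listed at 0 in Ngn3-negative. The genes farthest below included the pancreatic enzyme genes Prss2 (0.647 against 24.9), Ctrb1 (3.08 against 53.4), Pnlip (1.44 against 24.99) and Cpa1 (0.904 against 18.1), the enterocyte gene Clca4a (11.1 against 179.4), the nucleoside transporter gene Slc28a2 (5.63 against 70.3), Lars2 (126.1 against 1287) and Cyp2c29 (7.45 against 78.9). H2-Bl, at 17.6 against 197, and Amy2b, at 0.0499 against 11.4 and annotated as a pseudogene, belong to families of close copies and are uncertain. Dnase1, Chchd1, Tk1, Ang, Cela2a, Nipa2, Ydjc, Gins2, Exosc8, Fam118b, Exosc6 and Dnajc19 were listed at 0 in Ngn3-TOMATO.

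**Figure D1:**
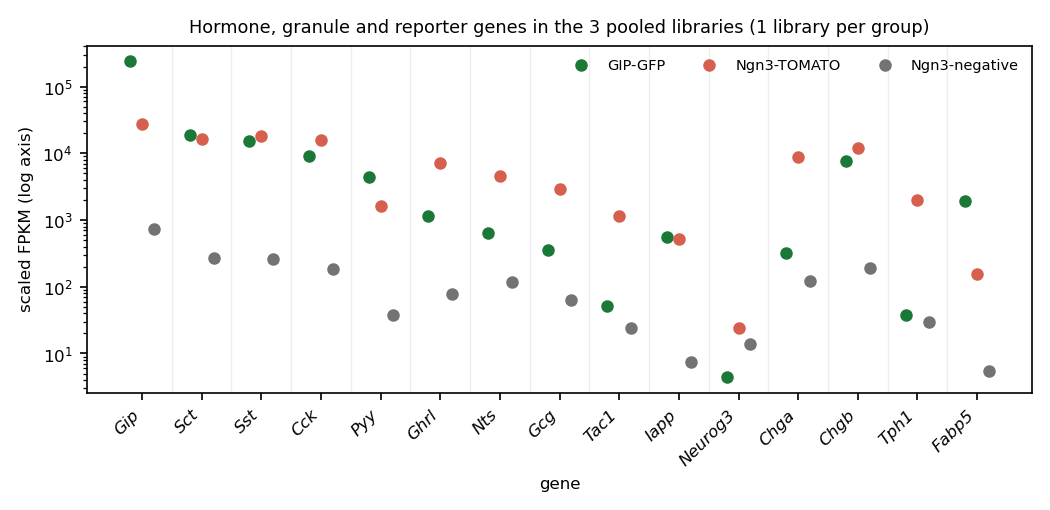
Scaled FPKM (log axis) of hormone, granule and reporter genes and of Tph1 and Fabp5 in the 3 libraries, 1 point per library and gene, with no error bars. Gip reaches 239500 in GIP-GFP, Ghrl and Chga are highest in Ngn3-TOMATO, and among these genes Neurog3 alone is lowest in GIP-GFP.

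The next comparison set GIP-GFP against Ngn3-negative, 2 sorts from different mouse lines, to show what marks the GIP-GFP sort among epithelial cells. GIP-GFP held more transcripts of other hormones besides Gip, of secretory granules and of glucose sensing, and of the fatty acid binding protein gene Fabp5. A pooled library cannot show whether the other hormones came from the cells that held Gip. With the pseudocount, Fabp5 was nearly as far above Ngn3-negative as Gip. Without it the ratios were 348 for Fabp5 and 331 for Gip, and larger for Alpl, Cnr1 and Fam167a, which were below 1 scaled FPKM in Ngn3-negative. Gip was 330-fold higher (log2 8.37, 8.33 to 8.41) and Fabp5 (uc008opg.1, chromosome 3, 10012606 to 10016610) was 295-fold higher, at 1918 against 5.51 scaled FPKM (log2 8.20, 7.86 to 8.54). Goblet, Paneth, tuft, enterocyte and cell cycle genes were all lower in GIP-GFP by list median. Over 13459 genes, 2839 were at least 2-fold higher and 1855 at least 2-fold lower, with 1369 and 373 past 4-fold. Of these 2-fold differences 60.5% were in the higher direction, against 51.2% under equal totals. With a pseudocount of 5 the genes at least 2-fold higher numbered 1793. Of the 2839 higher genes 299 were listed at 0 in 1 library, as were 106 of the 1855 lower.

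Of 15 measured hormone genes 12 were higher, with a median log2 ratio of 3.86. Pyy was at 4342 against 38.4, Sct, the secretin precursor, at 18880 against 272.6, and Iapp, the amylin precursor, at 560.8 against 7.43. All 18 granule genes were higher, with a median of 5.31 and the highest ratios for the prohormone-trimming enzyme gene Cpe (5259 against 28.6) and Scg2 (2024 against 13.5). The exocytosis list had a median of 2.84 with 19 of 24 higher, 1 lower and the highest ratios for Rimbp2 (234.1 against 3.30) and Syp (162.7 against 2.62). Transcription factors had a median of 3.27 with 23 of 26 higher and 1 lower. Rfx6 was at 1059 against 6.56, Isl1 at 767.3 against 3.22 and Pax6 at 499.2 against 3.07, and all of these also act in pancreatic islets. In the glucose sensing list, 23 of 29 genes were higher and 3 lower with a median of 3.33. Abcc8 and Kcnj11, which form the ATP-sensitive potassium channel, were at 442.3 against 1.89 and 119.7 against 1.13.

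The genes highest over Ngn3-negative also included Rgs4, a regulator of G protein signaling (1054 against 3.35), Rbp4, a retinol carrier (2367 against 9.01), Cnr1, the cannabinoid receptor (uc008sfw.1, chromosome 4, 33924632 to 33948831; 337.6 against 0.698), Fam167a (340.9 against 0.807), Sphkap (321.8 against 1.06) and the alkaline phosphatase gene Alpl (241 against 0.427). Nutrient sensing genes had a median of 1.44 with 10 of 19 higher and 3 lower. The lipid receptor genes Gpr119 (97.2 against 0.659) and Ffar1 (116.4 against 1.70) were higher, and the most abundant member, Slc5a1, was lower (494.2 against 1015). Hormone and transmitter receptors had a median of 1.39 with 12 of 23 higher and 3 lower. The muscarinic receptor gene Chrm4 (140.9 against 0.579) and the prostaglandin receptor gene Ptger3 (107.1 against 0.490) were higher, and the most abundant member, Vipr1, was lower (29.0 against 143.2). These 2 lists fell inside the random range when no filter on low values was used. The fatty acid binding protein list went both ways: Fabp5 and Fabp4 (44.3 against 0.168) were higher, Fabp2 (2863 against 11130) and Fabp6 (171.6 against 811.6) were lower, and its median of -1.75 over 5 genes changed sign without the filter and with shared transcript ends. That list fell inside the random range with the most abundant transcript and with shared transcript ends. The serotonin list had a median of 1.06 with 7 of 13 higher and 1 lower, and Tph1 itself was at 38.1 against 29.7. The neuron list had a median of 3.36 with 7 of 8 higher, led by the catecholamine enzyme gene Th (234.8 against 0.925).

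Lists for other epithelial cells had medians below 0. The median was -1.89 for the brush border, with 28 of 34 genes lower and 1 higher, and -1.57 for lipid absorption, with 22 of 34 lower and 5 higher. It was -1.86 for goblet cells (17 of 20 lower), -1.20 for Paneth cells (11 of 18 lower, 1 higher) and -1.30 for tuft cells (14 of 20 lower, 1 higher). The stem cell list had a median of -0.90 with 10 of 22 lower and 4 higher, and the cell cycle list -1.79 with 32 of 33 lower. Zg16 was at 1950 against 15640 and Lgr5, a stem cell gene, at 3.94 against 21.2, whereas Cd44 was higher (401.2 against 21.3) and so was the amino acid transporter gene Slc6a19 (925.3 against 303.8). Erythroid genes had a median of -2.72, the Reg family -1.70 and oxidative phosphorylation -0.87, the last inside the random range when only matches sharing a transcript end were used. Immediate early and unfolded protein response genes had medians of 0.52 and 0.46. Lymphocyte genes had a median of 0.78, at percentile 93.3, with Gzma, a lymphocyte granule protease, at 241.1 against 93.8. MHC class II, myeloid, B cell, stroma, Notch, housekeeping and epithelial identity lists, with medians of -0.18, 1.25, -0.31, 0.59, 0.05, -0.55 and -0.85, were inside the random range, and the Notch median was below 0 under equal totals. The single genes farthest below included the gastric genes Tff1 (2.67 against 100.2), Tff2 (1.58 against 55.2), Gkn1 (0.804 against 30.7) and Gkn2 (3.97 against 74.2), the pancreatic genes Prss2, Ctrb1, Cpa1 and Pnlip, and the calcium-binding protein gene S100g (87.1 against 1176). Scgb1a1, Tk1, Gfm2, Ang, Cela2a, Usmg5, Mrps18b, Cdc20, Bri3, Ydjc, Hyi and Gins2 were listed at 0 in GIP-GFP.

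**Figure D2:**
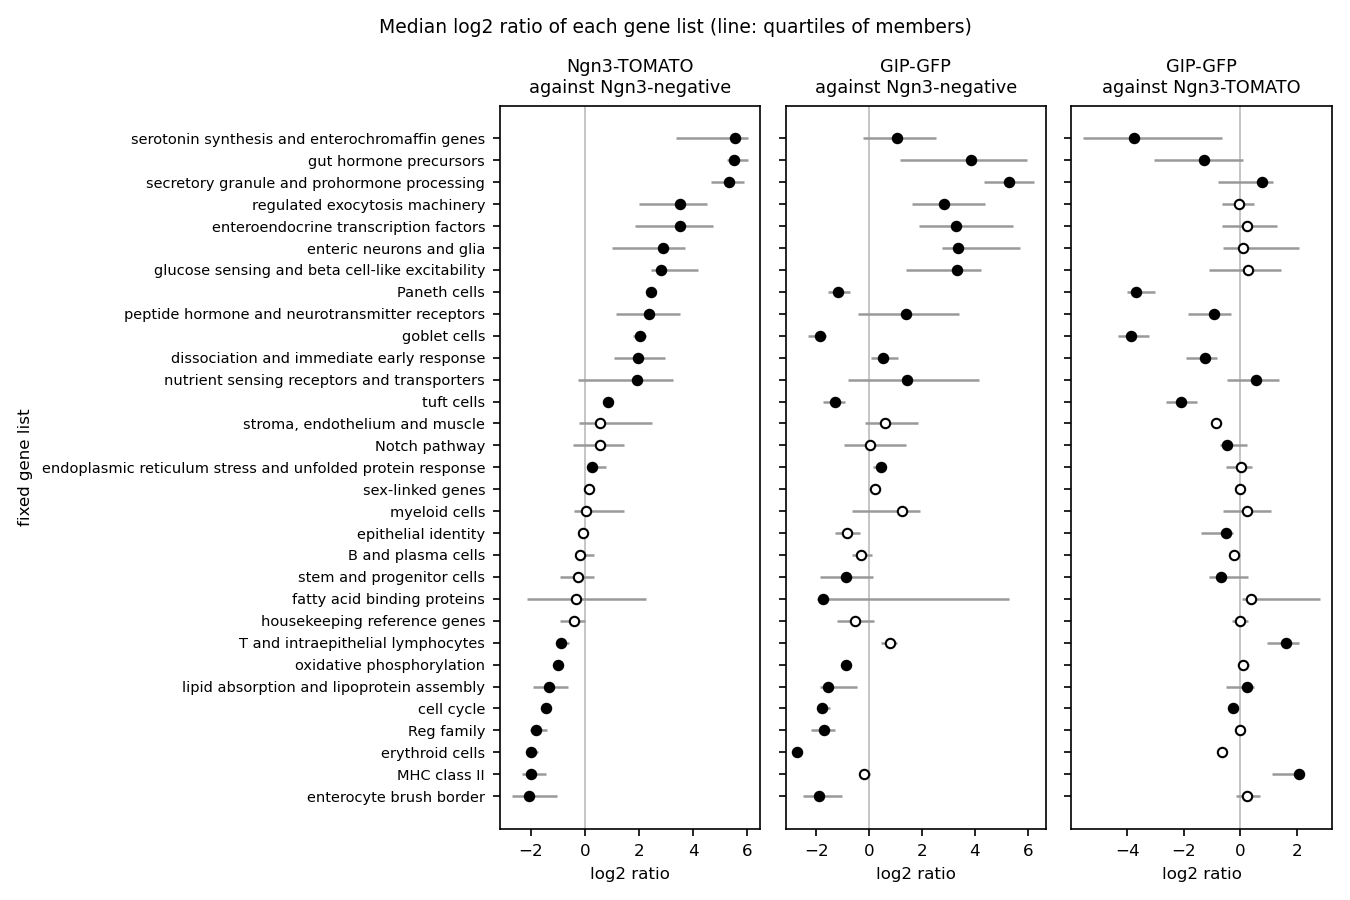
Median log2 ratio of each of the 31 fixed gene lists in the 3 comparisons, with lines for the quartiles of members and filled points for medians outside the middle 95% of 10000 matched random lists. Goblet and Paneth cell lists lie above 0 for Ngn3-TOMATO against Ngn3-negative (2.04 and 2.44) and below 0 for GIP-GFP against Ngn3-negative (-1.86 and -1.20).

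The last comparison, GIP-GFP against Ngn3-TOMATO, sets GIP cells beside the whole Ngn3-TOMATO sort, which comes from a different mouse line. Ngn3-TOMATO also held many goblet and Paneth cell transcripts. A ratio can therefore reflect the mix of cells in each sort or the line, which were not separated. GIP-GFP had 8.62-fold more Gip and 12.4-fold more Fabp5, while Tph1, Ghrl and Gast were lower in it. The transcription factor and glucose sensing lists went both ways. Goblet and Paneth cell genes were lower by medians of 14.6-fold and 12.8-fold. Over 13728 genes, 1104 were at least 2-fold higher and 1201 at least 2-fold lower, with 285 and 441 past 4-fold. With a pseudocount of 5 these 2-fold counts were 603 and 674. Of the 1104 higher genes 96 were listed at 0 in 1 library, as were 157 of the 1201 lower.

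Among hormone genes 2 of 17 were at least 2-fold higher in GIP-GFP and 10 at least 2-fold lower, with a median of -1.29. Pyy was at 4342 against 1618. Sct (18880 against 16540) and Sst (15300 against 18280) were within 2-fold, and Cck was at 9204 against 15850. Ghrl was at 1135 against 7284, Ucn3 at 3.44 against 135.7, Tac1, the substance P precursor, at 51.3 against 1149 and Gast at 25.9 against 670.8. The serotonin list had a median of -3.75 with 10 of 14 lower and 1 higher. Reg4 was 117-fold lower (102.7 against 12100; log2 -6.87, -6.98 to -6.75), Cartpt 114-fold lower, Trpa1 76.3-fold lower and Tph1 51.0-fold lower. Chga, at 319.8 against 8766, went apart from most granule genes, whose list median was 0.77 with 6 of 18 higher and 4 lower, while Chgb was at 7606 against 12000. The exocytosis list had a median of -0.04, inside the random range, with Rab3c at 0.576 against 58.0 and its most abundant member, Rimbp2, at 234.1 against 123.2.

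Rfx6 and Isl1 were higher in GIP-GFP by log2 ratios of 2.37 and 2.38, and Lmx1a, a factor of enterochromaffin cells, was lower (2.62 against 134.7), within a transcription factor list with 8 of 27 higher and 5 lower, whose median of 0.25 was inside the random range. Abcc8 was at 442.3 against 82.2, in a glucose sensing list with 9 of 29 higher and 8 lower, whose median of 0.28 was also inside it. Nutrient sensing genes had a median of 0.55 with 8 of 19 higher and 4 lower. Cnr1 was at 337.6 against 23.9, Gpr142, an amino acid receptor gene, at 39.9 against 6.93 and Gpr119 at 97.2 against 20.1, whereas Ffar2 was lower (6.41 against 108.5). Receptors for hormones and transmitters had a median of -0.95 with 13 of 26 lower and 3 higher, although Chrm4 and Ptger3 were higher (140.9 against 21.1 and 107.1 against 16.0). Of 6 fatty acid binding protein genes 2 were higher, Fabp4 (44.3 against 2.23) and Fabp5 (1918 against 154), and 1 was lower, with a list median of 0.39, inside the random range. Of 34 lipid absorption genes 3 were higher, among them Scarb1 (420.9 against 97.6), 3 were lower and 28 lay between. That list had a median of 0.25, above the random range except with the most abundant transcript or with shared transcript ends. Beside Fabp4, Fabp5 and Cnr1, the genes highest over Ngn3-TOMATO included Ccdc42 (52.2 against 0.580), the lipoprotein lipase gene Lpl (44.2 against 1.961), Sprr2b, Alpl, Padi2, Slfn2, Ecel1 and Pcsk2os2. The last of these is antisense to another gene and its reads cannot be assigned to a strand.

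At the other end stood Afp (16.6 against 1830), Tpbg (2.48 against 268.8), Slc38a11 (2.31 against 165.9), Gsdma (1.28 against 108.7), Serpina1e (4.14 against 214) and Zg16 (1950 against 89110). Tpsg1, Tm7sf2, Nfkb2, Ins2 and Gfm2 were listed at 0 in GIP-GFP. Listed at 0 in Ngn3-TOMATO were Chchd1, Nme9, Psd, Ugt1a6a, Dnase1, Ntan1, Bbip1, Thyn1, Fbxl2, Trmt112, Cdc37l1 and Sirt3. Of 19 goblet cell genes 18 were lower, of 18 Paneth cell genes 16 and of 21 tuft cell genes 20, with a tuft median of -2.11. Lymphocyte genes were higher in GIP-GFP for 14 of 20 and lower for 1, with a median of 1.61, and MHC class II genes for 6 of 7, with a median of 2.08. Gzma was at 241.1 against 35.8 and Cd74 at 316.6 against 63.4, and of these 2 sorts only the Ngn3-TOMATO sort was stated to exclude cells with CD45. Ngn3-negative was sorted with that gate too. Against it, MHC class II genes had a median of -0.18 in GIP-GFP and -2.0 in Ngn3-TOMATO. Immediate early genes had a median of -1.26 with 17 of 26 lower and 1 higher. The epithelial identity, stem cell, Notch and cell cycle lists had medians of -0.52, -0.70, -0.46 and -0.27, below the random range. The brush border, myeloid, B cell, stroma, neuron, erythroid, oxidative phosphorylation and housekeeping lists had medians of 0.22, 0.22, -0.23, -0.88, 0.10, -0.67, 0.08 and -0.01, inside it. The unfolded protein response and Reg family medians of 0.02 and -0.01 were also inside it. The housekeeping, unfolded protein response and Reg family medians changed sign under at least 1 other scaling.

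**Figure D3:**
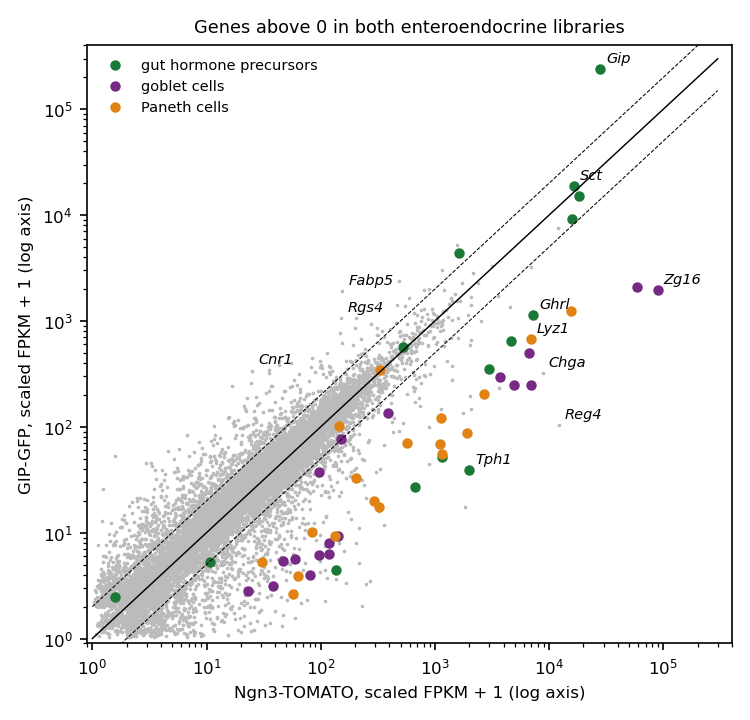
Scaled FPKM plus 1 of each gene above 0 in both enteroendocrine libraries, Ngn3-TOMATO on the horizontal and GIP-GFP on the vertical log axis. Lines mark equality (solid) and 2-fold (dashed), colored points are hormone, goblet and Paneth list members, Gip, Fabp5, Rgs4 and Cnr1 lie above the lines, and Zg16, Reg4, Tph1, Lyz1 and Chga lie below them.

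Across all 3 libraries, 1753 genes were at least 2-fold higher in both GIP-GFP and Ngn3-TOMATO than in Ngn3-negative. Among 13923 genes, 2583 and 2839 passed 2-fold in the separate comparisons, and independent lists of these sizes would share 527. In the lower direction 1049 genes were shared, against 177 for independent lists. Simulated libraries without differences shared a mean of 3.6 genes in the higher direction and 2.0 in the lower, which covers counting error only and not differences between mice, sorts or lines. Both comparisons use the same Ngn3-negative library, which cannot be split, and a shared control adds to such an overlap. Genes high in both included Iapp, Resp18, Gpx3, Scg2, Sct and Sst. In GIP-GFP 935 genes were at least 2-fold above both other libraries, among them Fabp5, Cnr1, Alpl, Lpl and the metabolic kinase gene Pdk4 (420.9, against 41.9 in Ngn3-TOMATO and 35.0 in Ngn3-negative). In Ngn3-TOMATO 744 genes were, among them Reg4, Trpa1, Cartpt, Tph1, Ucn3 and Chga, and in Ngn3-negative 1049, among them Clca4a, S100g and Slc28a2.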

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

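The search for unannotated transcripts was set up after the data were seen. Of the transcripts that match no gene of the annotation, which enter no comparison above, 2 were at 10 scaled FPKM or more in both reporter libraries and at least 4-fold above Ngn3-negative, the control library. The transcript uc009njr.1 (chromosome 8, 109986052 to 109986756, spliced length 273 bases) was at 46.65 scaled FPKM in GIP-GFP, 11.7 in Ngn3-TOMATO and 1.01 in Ngn3-negative. The transcript uc009jzq.1 (chromosome 7, 129919029 to 129924642, spliced length 757 bases) was at 30.75, 12.7 and 1.01. No explanation was tested for either.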

How the results depend on the processing

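With 1 library per group, only settings of the calculation could be varied, and the inclusion of short transcripts, the restriction to shared transcript ends and the removal of genes listed at 0 were chosen after the data were seen. The counts of genes past 2-fold, the patterns over 3 libraries and the numbers of lists outside the random range gave 194 alternative values, of which 187 stayed within 1.5 times the reported count. The other 7 came with a pseudocount of 5, which shrinks the ratios of low genes by construction. The genes at least 2-fold higher then numbered 1499 for Ngn3-TOMATO and 1793 for GIP-GFP against Ngn3-negative, and 603 for GIP-GFP against Ngn3-TOMATO, with 674 lower. Genes above both other libraries numbered 522 in GIP-GFP and 429 in Ngn3-TOMATO, and genes above Ngn3-negative in both reporter libraries 974. Of 1113 alternative list medians 50 left the interval of resampled members, and for lists outside the random range 2 changed sign: the fatty acid binding proteins in GIP-GFP against Ngn3-negative stood at 0.52 without the filter and 0.56 with shared transcript ends, against -1.75, and the cause was not tested. Of 4786 alternative values of named genes 788 left their counting interval, and among genes at least 2-fold apart 1 changed sign: Cadps, in the same comparison, was at -1.19 when only transcripts with status OK were used, against 5.09, because its estimates in GIP-GFP had another status and were then set to 0. Scaling to equal totals shifted the median of all genes by -0.23 and -0.20 in Ngn3-TOMATO and GIP-GFP against Ngn3-negative, the median ratio by 0.10 and 0.05, and equal totals without the most abundant genes by 0.14 and 0.16. Of the lists outside the random range, 22 of 22, 18 of 22 and 15 of 16 stayed outside under all alternatives run, in the order Ngn3-TOMATO against Ngn3-negative, GIP-GFP against Ngn3-negative and GIP-GFP against Ngn3-TOMATO. The setting on overlapping limits gives no list median. Some genes with many near-copies in the genome had values too low to use, such as Gapdh, which was at 0.431, 0.402 and 0.893 scaled FPKM in GIP-GFP, Ngn3-TOMATO and Ngn3-negative. The GIP-GFP library was the least deep, which limits what can be read from its low genes.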

Other observations

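The tests of explanations and their bounds, and the genes of other organs, were chosen after the results were seen, whereas the gene lists and the 3 other scalings had been fixed in advance. Some genes best known from pancreas or stomach were higher in Ngn3-negative, but they were picked for their values, no fixed list covers these organs, and the origin of the transcripts was not tested. Beside the pancreatic enzymes named earlier, Cela2a was at 54.3 scaled FPKM and listed at 0 in the other libraries. The genes Tff1, Tff2, Gkn1, Gkn2 and Gkn3 were at 100.2, 55.2, 30.7, 74.2 and 50.5 in Ngn3-negative, at 16.5, 12.7, 3.02, 8.78 and 23.8 in Ngn3-TOMATO, and at 2.67, 1.58, 0.804, 3.97 and 10.7 in GIP-GFP. Scgb1a1 was at 140.7 in Ngn3-negative, 28.6 in Ngn3-TOMATO and listed at 0 in GIP-GFP.

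Some genes of serum proteins, and insulin genes, were higher in Ngn3-TOMATO, picked in the same way and not tested as a group. Afp was at 1830 scaled FPKM there, against 16.6 in GIP-GFP and 15.2 in Ngn3-negative. Serpina1e was at 214, 4.14 and 3.25 in the same order, and Alb, the albumin gene, at 41.7, 4.62 and 0.245. The insulin genes Ins2 and Ins1 were at 55.1 and 7.36 in Ngn3-TOMATO and listed at 0 in both other libraries, where an exact 0 can be a failed estimate. Of the mitochondrial transcripts, which entered no comparison, mt-Rnr1, mt-Rnr2 and mt-Nd2 had a value above 0 in each library. They were at 38360, 33900 and 32530 in Ngn3-negative, 4135, 5833 and 8550 in Ngn3-TOMATO, and 2447, 8812 and 15480 in GIP-GFP.

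Goblet and Paneth cell genes were higher in Ngn3-TOMATO than in the population that the design text describes as holding these cell types. The 3 other scalings do not account for it, since the lowest of the list medians under them was 1.80. Their factors lay between 0.933 and 1.11 and could move a median only slightly, so a larger error of scaling was not tested. A carry-over of Ngn3-negative material as a whole cannot raise a gene above its source, so the pattern itself, with a lower quartile of the members' log2 ratios of 1.86, speaks against it, and no separate test was made. Granular cells taken into every reporter sort would also raise these genes in GIP-GFP, where the higher of the list medians against Ngn3-negative was -1.20. The lineage label itself, if goblet and Paneth cells are among the cells that carry it, and a gate peculiar to the tomato sort stay open and were not tested, since pooled libraries cannot show which cells held the reporter.

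Lymphocyte genes were higher in GIP-GFP than in Ngn3-TOMATO, and of the 24 on the list, 19 were at 1 scaled FPKM or more in Ngn3-negative and 0 stood in another list. Under the 3 other scalings the lowest list median was 1.59, so none of these accounts for it, and a larger error of scaling was not tested. Lymphocytes among the sorted GIP-GFP cells would bring their abundant transcripts. Of 17 list members at 5 scaled FPKM or more, 12 were at least 2-fold higher, short of the 75% set as the bound. Gzma was at 241.1 and Ccl5 at 144.1 in GIP-GFP. These ratios are the ones that gave the pattern, and the bound was set after they were seen, so the share decides neither way. The CD45 gate stated for the tomato sorts only would remove such cells there, but Ngn3-negative, sorted with that gate, held Gzma at 93.8 and lay below GIP-GFP by a list median of 0.78 only. Contaminating lymphocytes and a difference between mouse lines cannot be told apart, because the line and, as far as stated, the gate differ together.

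Enterocyte brush border genes were below Ngn3-negative by medians of -2.07 in Ngn3-TOMATO and -1.89 in GIP-GFP, and were still abundant, with Rbp2 at 1144 and 3028 scaled FPKM; 3 of the 34 genes stood in another list. The 3 other scalings do not account for the difference, since the highest list median under them was -1.73, and a larger error of scaling was not tested. Carry-over of enterocyte RNA into both sorts at 1 mixing share would give the members 1 common ratio. Within 1 log2 unit of the list's median lay 64.7% of members in Ngn3-TOMATO and 73.5% in GIP-GFP, between the bounds set for and against. Slc6a19, named after its value was seen, was at 925.3 in GIP-GFP against 303.8 in Ngn3-negative. Carry-over from cells at the Ngn3-negative level cannot give that value, but enterocytes of the GIP-GFP mouse line were not measured. Carry-over and expression by the enteroendocrine cells themselves cannot be told apart, because these shares decide neither way.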
